A study of Arabidopsis thaliana with 21 samples.

How the data were processed

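Whole roots of Arabidopsis thaliana seedlings were measured on 21 one-colour Agilent arrays in 7 groups of 3, which the series design calls biological replicates. Per the labels, seedlings grew for 7 days on agar before transfer to medium with 11.4 mM N (control; 0, 1, 2 and 4 days) or 0.55 mM N (low N; 1, 2 and 4 days), and RNA was purified on columns with DNase treatment and labelled with Cy3. Groups and replicate numbers were taken from the labels.

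The scanner values are linear spot intensities made with Agilent Feature Extraction 11.5.1.1, per the file headers; the processed intensity is background-subtracted and spatially detrended within each array and not normalized between arrays. The authors also deposited a table of log2 values, used here only as an alternative. The submitters' processing notes name Agilent Feature Extraction and limma, while its background correction, normalization and choice of probes are not given in the sources used here. Its column medians lay between 7.8313 and 7.8823, its columns correlated with the scanner values at 0.9735 to 0.9824 across probes, and a difference between 2 arrays correlated at 0.7735 with that of the scanner values.

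The value analysed was log2 of the processed intensity minus the array's 75th percentile. Control spots were left out, spots flagged as outliers were set to missing (220 values, filled with the group mean for list tests only), and spots of the same probe were averaged. Of 43603 probes, 35597 carry a RefSeq accession and 34348 matched 1 locus in a reference list of genes of the TAIR10.1 assembly, used for names only; 9255 did not match and were tested apart. A probe was kept if well above background on all measured arrays of at least 1 group. Each locus was represented by its brightest kept probe, giving 20882 genes, 6262 of which had more than 1 kept probe. All kept probes had the same sign for 187 of 216 such genes called at day 1, 186 of 194 at day 2 and 326 of 344 at day 4. Where a probe was not well above background on any array of a group, the fold is a lower bound against the lowest signal well above background. The number of arrays per group limits the precision.

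Tests were run in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. One linear model with a mean per group was fitted to all 21 arrays (14 residual and 1.86 prior degrees of freedom), followed by limma's empirical Bayes test, two-sided. The comparisons were low N against control at each day, their average over days, the difference of this effect between days (F test), and the control days against each other (F test and against day 0). Each p was adjusted by Benjamini-Hochberg within its comparison, and genes with an adjusted p under 0.05 are called. SE is the standard error of the log2 fold change from limma, and SD that between the 3 arrays.

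Sets of genes were 27 lists, tested with limma's camera (preset correlation 0.01), with camera's estimated correlation and with fry. Camera compares a list with other genes; fry asks whether its members move one way on balance. List members were entered as locus codes and names from general knowledge. Named genes are, for each day, the 8 highest and 8 lowest called genes with a symbol whose low N arrays all lay beyond all control arrays, up to 3 called members with the smallest adjusted p of each list, and 14 genes named in advance. For the average, the day differences and the control time course they are the 6 highest and 6 lowest called genes with a symbol. Groups, tests, named-gene rule, lists and most alternatives were chosen before the data were examined. The alternatives were array weights, normexp with offset 50 and quantile normalization, quantile normalization, median centring, the deposited table, no filter, a filter on all arrays, the mean of a gene's probes, leaving out each array, fitting only the groups compared, blocks for replicate number, slide and scan day, a 2-fold threshold, and a trended robust empirical Bayes test. The normexp alternative used the median spot intensity and the median background intensity of the scanner files. Chosen after the data were seen were the share of spots well above background as a covariate, leaving out the 3 arrays that stand apart, scan day as a fixed block, the test of unmatched probes and the limit on signal that NRT2.2 could share with NRT2:1.

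The procedure was tested on simulated data made from the 20882 genes. At day 1, 56.7%, 92.5% and 93.9% of genes changed by 0.5, 1 and 2 on the log2 scale were called and 2.99% of calls were false. The values were 52.2%, 85.1%, 98.5% and 2.48% at day 2, and 53.7%, 77.6%, 93.9% and 3.85% at day 4. These simulations held no slide effect.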

Results

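Transcript levels were measured in whole roots of Arabidopsis thaliana seedlings on 21 one-colour microarrays, each holding 1 Cy3-labelled RNA sample. Seedlings were raised on agar and moved to agar with 11.4 mM nitrogen (N), the control, or with 0.55 mM N. The latter, called low N here, is a mild deficiency per the series design. Control roots were sampled at 0, 1, 2 and 4 days and low N roots at 1, 2 and 4 days, with 3 biological replicates in each of the 7 groups. For low N, rose and fell mean higher and lower than in control roots of the same day, not changes since day 0. Between 69.9% and 95.1% of the spots of an array were well above background, the 75th percentile of the signal ranged from 679 to 2021, and no spot was saturated. Log2 values of replicate arrays correlated at 0.98 to 0.997 across genes. The arrays came from 9 slides scanned on 6 days. Component 1 of a principal component analysis, with 28.6% of the variance, set apart control day 1 replicate 3 (88.9% of spots well above background), low N day 2 replicate 3 (95.1%) and low N day 4 replicate 1 (88.8%). Counts of genes are therefore also given without these 3 arrays, a check chosen after the arrays were seen. Of 29 camera calls of lists at days 1, 2 and 4, 25 held without them.

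**Figure D1:**
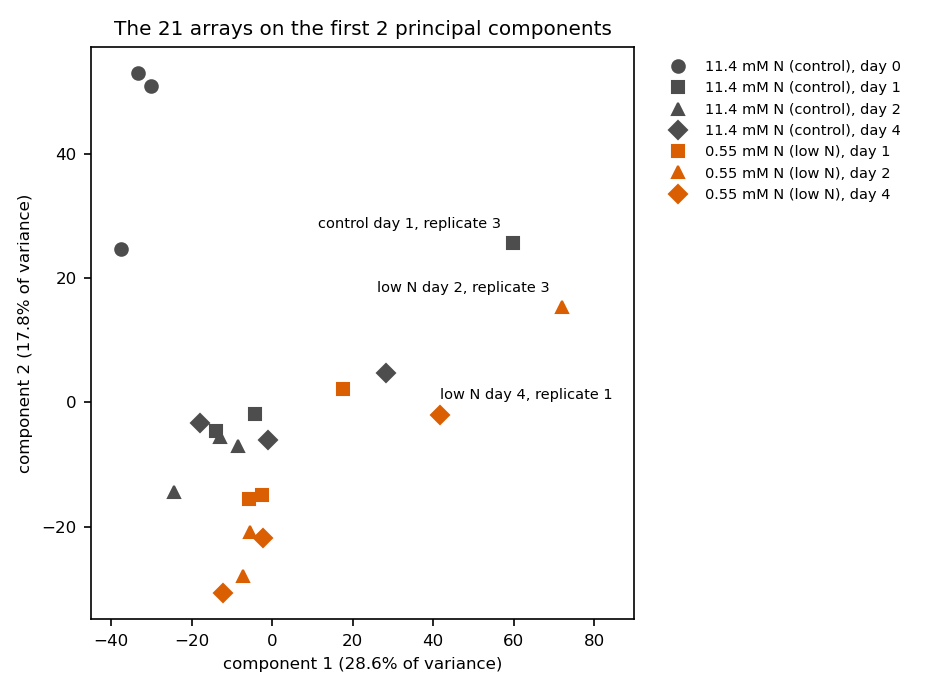
Each symbol is 1 array, placed by its score on component 1 (28.6% of the variance) and component 2 (17.8%), with control arrays in grey, low N arrays in orange and the symbol giving the day. The 3 named arrays lie far to the right, and the 3 control arrays of day 0 lie to the upper left.

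After 1 day on low N, the high-affinity nitrate transporter genes NRT2.4 and NRT2:1 were higher than in control roots of the same day. The nitrate transport list as a whole was not called by camera (adjusted p = 0.318), while fry called it up (adjusted p = 0.002). NRT2.4 rose by 2.64 on the log2 scale (standard error (SE) 0.19, n = 3 per group, adjusted p = 3.45e-06), which is 6.23-fold. NRT2:1, the main high-affinity nitrate transporter of roots, had a scaled log2 signal of 5.66 ± 0.14 (SD, n = 3) on low N and 3.41 ± 0.27 on control medium, which is a log2 fold change of 2.25 (SE 0.17, adjusted p = 3.45e-06). WR3, the NRT3.1 partner protein of these transporters, rose by 1.15 (SE 0.11, adjusted p = 4.44e-05). SKOR, the potassium channel that loads the xylem, fell by 2.63 on the log2 scale (SE 0.22, adjusted p = 1.34e-05), and the anion channel gene SLAH1, well above background on 2 of the 3 low N arrays, fell by 2.25 (SE 0.35, adjusted p = 0.0025). IRT1, the iron transporter of the root epidermis, fell by 1.8 (SE 0.46, adjusted p = 0.0439).

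Other genes with large increases at day 1 were the UmamiT-family transporter genes UMAMIT36 (2.64, SE 0.27, adjusted p = 6.7e-05) and UMAMIT35 (1.92, adjusted p = 0.0072). The glutathione transferase gene GSTF14 (1.38, adjusted p = 1.26e-05) and FAF4 (1.19, adjusted p = 0.000816) also rose. NRT2.2 had a log2 fold change of 6.04 (SE 0.88, adjusted p = 0.0012). Its probe was well above background on only 2 of the 3 control arrays. Its sequence is nearly that of NRT2:1. Were its low N signal shared signal of NRT2:1 alone, rising as that gene's own probe did, its control level would be -4.08, -3.10 and -3.57 at days 1, 2 and 4. The highest control array, or the lowest signal well above background on an array where that was higher, lay at -6.01, -6.61 and -5.94, so that some but not all of the low N signal could be shared. The size of the fold change stays uncertain with control values near background. Genes that fell included GAT1_2.1, a glutamine amidotransferase-like gene (-2.06, adjusted p = 0.0048), the ferric reductase gene FRO4 (-1.73, adjusted p = 0.0164), the carbonic anhydrase gene ACA1 (-1.58, adjusted p = 0.0274) and the glucosyltransferase gene UGT71B8 (-1.54, adjusted p = 0.0093, well above background on 2 of 3 low N arrays). MIOX4, a myo-inositol oxygenase, was not well above background on low N at day 1 and was at least 1.58-fold lower there (adjusted p = 0.0156). Among genes named beforehand, NIA1, encoding a nitrate reductase, rose by 0.40 (SE 0.09, adjusted p = 0.0263) and BSK3, a brassinosteroid signalling kinase, by 0.23 (SE 0.06, adjusted p = 0.0338) on the brighter of its 2 probes, the other being at 0.0104. Values that did not pass were 0.35 for the nitrite reductase gene NIR1 (adjusted p = 0.0844). They were 0.31 for the dual-affinity transporter and sensor NRT1.1 (0.151) and 0.29 and 0.24 for the auxin synthesis genes TAA1 (0.0716) and TAR2 (0.182). The root hair regulator RSL2 was at 0.36 (0.102). Other values were 0.14 each for YUC8 and DWF1, 0.03 for AUX1 and -0.04 for RSL4. NRT2.5 was not well above background and was not tested.

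Of 27 gene lists fixed beforehand, 9 differed from other genes at day 1 in limma's camera test with its preset correlation of 0.01. Of these, 4 were up and 5 down. With an estimated correlation none passed, though 6 had an unadjusted p under 0.05, and limma's fry test called 8. Among fry's calls were nitrate transport and root hair patterning, which camera did not call. Fry did not call phosphate starvation response and nitrate signalling (fry adjusted p = 0.0726 each) or sulfate uptake (0.2998). Ammonium, urea and amino acid transport rose as a group (2 of 10 members rose over all genes and 6 when adjusted over the list alone, median 0.31, adjusted p = 7.06e-05, adjusted p = 0.143 with an estimated correlation). The urea transporter DUR3 was at 1.01 (SE 0.13, adjusted p = 0.00042) and the ammonium transporter AMT2 at 0.35 (adjusted p = 0.028). Nitrate reduction and assimilation rose (6 of 25 up and 1 down, 10 and 3 adjusted over the list alone, median 0.14, adjusted p = 0.0043, adjusted p = 0.209 with an estimated correlation). The nitrate reductase gene NIA2 was at 0.58 (adjusted p = 0.000238), the glutamine synthetase gene GLN1;4 at 0.66 (adjusted p = 0.001) and the glutamate dehydrogenase gene GDH2 at -0.55 (adjusted p = 0.000775). The list's call ended with quantile or normexp normalization and in the deposited value table. Root hair growth rose (4 of 21 up, 7 adjusted over the list alone, median 0.30, adjusted p = 6e-06, adjusted p = 0.319 with an estimated correlation). The peroxidase gene RHS19 was at 1.07 (adjusted p = 0.008), the proton pump gene HA7 at 0.60 (adjusted p = 0.0366) and MRH6 at 0.55 (adjusted p = 0.0439). Cytosolic ribosomal proteins rose by little (3 of 18 up, 10 adjusted over the list alone, median 0.19, adjusted p = 3.19e-07, adjusted p = 0.143 with an estimated correlation). RPL23AA led with 0.32 (adjusted p = 0.0436), and this call ended under the same 3 alternatives.

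Cytokinin biosynthesis, breakdown and response fell at day 1 (6 of 21 down by either adjustment, median -0.20, adjusted p = 8.35e-06, adjusted p = 0.118 with an estimated correlation). CKX4, a cytokinin-degrading oxidase, was at -0.90 (adjusted p = 0.001) and IPT3, a cytokinin synthesis enzyme, at -0.79 (adjusted p = 0.0057). Iron acquisition fell (3 of 29 down; 13 down and 2 up adjusted over the list alone; median -0.26, adjusted p = 0.000139, adjusted p = 0.143 with an estimated correlation). The copper transporter COPT2 was at -1.02 (adjusted p = 0.0091) and the regulator bHLH38 at -1.10 (adjusted p = 0.018). Phosphate starvation response fell (4 of 24 down and 1 up, 7 and 2 adjusted over the list alone, median -0.13, adjusted p = 0.0277, adjusted p = 0.384 with an estimated correlation). The phosphate sensor SPX1 was at -1.53 (adjusted p = 0.000816) and the acid phosphatase PAP17 at -1.17 (adjusted p = 0.000611). Sulfate uptake fell (1 of 15 up and 1 down, 1 and 2 adjusted over the list alone, median -0.16, adjusted p = 0.0434, adjusted p = 0.541 with an estimated correlation). Its sulfate transporter SULTR1;1 rose by 0.86 (adjusted p = 0.0245). Nitrate signalling fell (1 of 23 down, 4 adjusted over the list alone, median -0.08, adjusted p = 0.0367, adjusted p = 0.295 with an estimated correlation). The repressor HRS1 was at -0.82 (adjusted p = 0.0026). Nitrate transport held 4 of 16 members that rose and 5 that fell (6 and 5 adjusted over the list alone, median 0.16) and was not called by camera (adjusted p = 0.318). Shoot and photosynthesis markers, included to look for other tissue, had negative values for 22 of 22 members (median -0.20, adjusted p = 0.0772), with none past the test. CEP and CLE peptide signalling, which links shoot and root N status, had 2 of 13 members up and 1 down and was not called (3 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.430). Those up were AT4G32950, listed as the phosphatase CEPH (2.05, adjusted p = 6.8e-05), and AT5G66815, listed as the peptide gene CEP5 (0.75, adjusted p = 0.0033). The receptor kinase gene CLV1 was down (-0.43, adjusted p = 0.0472). In the other 15 lists at most 1 member passed. One was the jasmonate repressor JAZ1 (-0.38, adjusted p = 0.0155) in the defence list, whose median was 0.01 while its test pointed down (adjusted p = 0.329). The median of the abscisic acid list was -0.06 and its mean 0.07, with a test pointing down (adjusted p = 0.701).

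In all, the genes changed by low N at day 1 numbered 651, 360 up and 291 down, with a median absolute log2 fold change of 0.485. At least 2-fold changes were seen in 78 of them, 33 up and 45 down. The share of calls that were up was 55.3%, and under some other settings most calls were down. There were 211 up and 240 down in the value table, 244 and 273 with the mean of a gene's probes, 136 and 159 with the share of spots well above background as a covariate, 156 and 162 with scan day as a random block, and 23 and 32 with only the groups compared. There were 142 and 179 without control replicate 2, 127 and 149 without low N replicate 2, and 128 and 141 without low N replicate 3. Leaving out 1 array at a time gave fewer calls for each of the 6 arrays. There were 414, 321 and 365 without control replicates 1, 2 and 3, and 303, 276 and 269 without low N replicates 1, 2 and 3. Without the 3 arrays that stand apart there were 312, 274 of them among the 651. No slide and no scan day held both groups of day 1. As a random block, slide gave 432 calls and scan day 318. As a fixed block, which compares the groups through other days, scan day gave 10 calls and slide gave 2. These were AT4G38340 (1.93) and AT1G72270 (1.08), named here after their values were seen. At an unadjusted p under 0.05 the slide fit held 1514 genes, against 3582 without the block and 1044 expected by chance. None of the 49 named calls of day 1 passed with slide as a fixed block, while scan day kept GDH2, GSTF14, NRT2:1, NRT2.4 and UMAMIT36. All 651 fold changes kept their sign in the slide fit, where the standard errors were 1.79 times as large in the median. IRT1 came to -0.34, and the medians of iron acquisition and root hair growth came to 0.0014 and 0.09. The calls of these lists and of sulfate uptake ended. The slide-block medians of the others were 0.27 for ammonium transport, 0.17 for assimilation and 0.17 for ribosomal proteins. They were -0.32 for cytokinin, -0.27 for phosphate and -0.10 for nitrate signalling. The call of RPS6 (0.22, adjusted p = 0.049) ended under 13 of 13 other settings and those of RPL23AA and RHD6 (0.34, adjusted p = 0.0474) under 11 of 13. The lowest values among probes were 0.036 for RPS6, 0.099 for RPL23AA and 1.68 for UMAMIT36.

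After 2 days NRT2.4 and NRT2:1 were again higher than in control roots of the same day. The nitrate transport list was again not called by camera (adjusted p = 0.244) but was called up by fry (adjusted p = 4.25e-05). NRT2.4 rose by 3.61 (SE 0.19, n = 3 per group, adjusted p = 3.66e-08), 12.2-fold, and NRT2:1 by 3.0 (SE 0.17, adjusted p = 4.77e-08), from 3.01 ± 0.13 on control medium to 6.01 ± 0.17 on low N (SD, n = 3). Compared with control roots of that day, NIA1 was higher by 0.98 (SE 0.09, adjusted p = 1.18e-05) and NIR1 by 0.72 (SE 0.10, adjusted p = 0.000727). These genes act in the first and the next step of nitrate reduction. On low N they averaged 4.83 and 5.08, below their highest day 0 arrays (5.01 and 5.40). Control roots of day 2 averaged 3.85 and 4.36. Among the named genes, the lowest fold change was that of SAG13, a senescence-associated dehydrogenase (-3.82, SE 0.59, adjusted p = 0.0012). It was followed by CYP71A12, a cytochrome P450 of indole defence compounds (-2.47, SE 0.41, adjusted p = 0.0022), and CKX2, a cytokinin oxidase (-2.27, SE 0.28, adjusted p = 0.000174). SAG13 was well above background on 2 of the 3 low N arrays.

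UMAMIT36 (3.79, adjusted p = 1.08e-06), UMAMIT35 (2.66, adjusted p = 0.000341), RL4 (2.03, adjusted p = 0.000324) and FAF4 (1.79, adjusted p = 1.14e-05) were also among the highest at day 2. So was NRT2.2 (7.99, adjusted p = 6.13e-05), whose probe was well above background on 1 of 3 control arrays. The potassium transporter HAK5 had a value of 2.05 at the edge of the test (SE 0.55, adjusted p = 0.05), and its call ended under 11 of 12 other settings. Its probe was well above background on 1 of 3 control arrays, and the value was 3.32 within the scan day that held both groups. SKOR (-2.11, adjusted p = 4.23e-05), the trypsin inhibitor gene KTI1 (-1.82, adjusted p = 4.75e-06), CCOAMT (-1.66, adjusted p = 0.0197) fell. The salicylic acid related defence genes ALD1 (-1.57, adjusted p = 0.0014) and CBP60G (-1.48, adjusted p = 0.0141) fell too. Values that did not pass were 0.42 for RSL2 (adjusted p = 0.0569), 0.26 for TAR2 (0.157), 0.10 for TAA1 (0.598) and 0.06 for BSK3 (0.665). They were 0.13 for RSL4, 0.23 for YUC8, 0.16 for DWF1, 0.07 for AUX1 and -0.21 for NRT1.1 (0.391). Only 1 of the 3 probes of DWF1, the brightest, had this sign at days 1 and 2.

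Camera called 11 of the 27 lists at day 2, 5 up and 6 down. None passed with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 8. Fry's calls included nitrate transport and root hair patterning, which camera did not call. They left out sulfate, iron and cytokinin (fry adjusted p = 0.194 each), suberin (0.414) and shoot markers (0.688). Root hair growth rose (7 of 21 up, 13 adjusted over the list alone, median 0.58, adjusted p = 2.58e-07, adjusted p = 0.273 with an estimated correlation). HA7 was at 0.87 (adjusted p = 0.0026) and the lipid transfer protein gene COW1 at 0.63 (adjusted p = 0.0074). Nitrate reduction and assimilation rose (9 of 25 up and 2 down, 13 and 2 adjusted over the list alone, median 0.26, adjusted p = 3.19e-05, adjusted p = 0.203 with an estimated correlation), GDH2 falling by 0.74 on the log2 scale (adjusted p = 2.92e-05). CEP and CLE peptide signalling rose (4 of 13 up and 2 down, 7 and 2 adjusted over the list alone, median 0.39, adjusted p = 0.0065, adjusted p = 0.228 with an estimated correlation). AT4G32950 was at 2.61 (adjusted p = 4.29e-06). AT2G23440, listed as the peptide gene CEP3, was at 1.96 (adjusted p = 0.0056, well above background on 1 of 3 control arrays), and AT1G72180, listed as the receptor gene CEPR2, at -0.31 (adjusted p = 0.0109). Ammonium, urea and amino acid transport rose (2 of 10 up, 5 adjusted over the list alone, median 0.21, adjusted p = 0.0011, adjusted p = 0.228 with an estimated correlation). DUR3 was at 1.21 (adjusted p = 4.48e-05) and the amino acid transporter LHT1 at 0.66 (adjusted p = 0.0179). The ribosomal list was called up with no member past the test (0 of 18, median 0.11, adjusted p = 0.0065, adjusted p = 0.400 with an estimated correlation). That call ended under each of 4 other scalings.

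Sulfate uptake fell at day 2 (1 of 15 down, 2 up and 5 down adjusted over the list alone, median -0.19, adjusted p = 0.0011, adjusted p = 0.392 with an estimated correlation). AT5G26220, listed as the glutathione-degrading GGCT2-1, was at -0.90 (adjusted p = 0.0127). The defence list fell (2 of 12 down, 1 up and 3 down adjusted over the list alone, median -0.11, adjusted p = 0.0011, adjusted p = 0.228 with an estimated correlation) through CYP71A12 and JAZ1 (-0.54, adjusted p = 0.000775). Iron acquisition fell (1 of 29 up and 2 down, 1 and 3 adjusted over the list alone, median -0.12, adjusted p = 0.0065, adjusted p = 0.278 with an estimated correlation). COPT2 was at -1.15 (adjusted p = 0.0023) and the ferritin gene FER4 at 0.32 (adjusted p = 0.0213). Cytokinin genes fell as a list (1 of 21 up and 3 down, 2 and 4 adjusted over the list alone, median -0.06, adjusted p = 0.0495, adjusted p = 0.392 with an estimated correlation). CYP735A1, which makes trans-zeatin, was at -0.49 (adjusted p = 0.0155) and the response regulator RR16 at 1.18 (adjusted p = 0.0094). Endodermal barriers and suberin (0 of 24, median -0.04, adjusted p = 0.0284, adjusted p = 0.400 with an estimated correlation) and shoot markers (0 of 22, median -0.21, 21 values negative, adjusted p = 0.0284, adjusted p = 0.634 with an estimated correlation) had no member past the test and were called down. Under other scalings the cytokinin and shoot calls ended with all 4, and the suberin call with quantile, normexp and the value table. Phosphate starvation response had 3 of 24 members up and 7 down (6 and 7 adjusted over the list alone) and did not pass (median -0.13, adjusted p = 0.0533). Nitrate transport had 4 of 16 up and 4 down (5 and 5 adjusted over the list alone, median 0.15, adjusted p = 0.244), and nitrate signalling 1 of 23 up and 3 down (2 and 6 adjusted over the list alone, median -0.01, adjusted p = 0.153). In the other 13 lists at most 1 member passed. Among these members were RHD6, a regulator of root hair fate (0.49, adjusted p = 0.0036), and GH3.3, an auxin-conjugating enzyme (-0.95, adjusted p = 0.0195). For the sugar and handling lists the medians were 0.11 and 0.03 while the tests pointed down (adjusted p = 0.855 and 0.138).

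The genes changed by low N at day 2 numbered 752, 421 up and 331 down, and 128 changed at least 2-fold. The share of calls that were up was 56.0% here, 41.0% with median centring, 43.4% in the value table, 45.8% with normexp and 46.4% with quantile normalization. Leaving out control replicates 1 or 3 gave 441 and 431 calls (the latter 211 up and 220 down) and leaving out low N replicates 2 or 3 gave 395 and 436, and without control replicate 1 only 7 lists were called. Without the 3 arrays that stand apart there were 382 calls, 360 of them among the 752. On the scan day that held all 3 low N arrays and 1 control array, which also entered the calls, the values were 3.93 for NRT2.4, 2.93 for NRT2:1, 1.09 for NIA1, -2.22 for SKOR and -1.99 for CKX2, and those of CBP60G and COPT2 came to -0.89 and -0.68. List medians within that day were 0.62 for root hair growth, 0.28 for assimilation, 0.28 for ammonium transport, 0.36 for CEP and CLE signalling and 0.08 for ribosomal proteins. They were -0.15 for sulfate, -0.20 for defence, -0.10 for cytokinin, -0.06 for suberin, -0.08 for shoot markers and 0.01 for iron. No slide held both groups of day 2. With slide as a random block 599 genes were called and with scan day 693. As fixed blocks, scan day gave 249 calls (217 shared) and slide 1, AT4G38340 (2.72), named after its value was seen. The slide fit held 1344 genes at an unadjusted p under 0.05, against 3181 without the block and 1044 expected by chance. The slide block ended all 43 named calls and those of root hair growth (median 0.27), ribosomal proteins (0.12), suberin (-0.04), iron (0.01) and sulfate (-0.04). Medians of the other lists were 0.25 for assimilation, 0.21 for ammonium transport, 0.42 for CEP and CLE signalling, -0.15 for cytokinin, -0.31 for defence and -0.36 for shoot markers.

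After 4 days NRT2.4 and NRT2:1 were again higher on low N. The nitrate transport list was not called by camera (adjusted p = 0.409) but was called up by fry (adjusted p = 2.58e-05). NRT2.4 rose by 4.55 (SE 0.19, n = 3 per group, adjusted p = 9.56e-10), 23.4-fold, and NRT2:1 by 3.88 (SE 0.17, adjusted p = 9.56e-10), 14.7-fold. The latter went from 2.07 ± 0.14 on control medium to 5.94 ± 0.06 on low N (SD, n = 3). WR3 rose by 1.68 (SE 0.11, adjusted p = 1.87e-07) and NIA1 by 1.54 (SE 0.09, adjusted p = 4.89e-08). ALMT1, the malate channel of the root tip, fell by 2.09 (SE 0.11, adjusted p = 5.85e-09), UMAMIT33 by 1.99 (SE 0.12, adjusted p = 8.1e-08) and CKX2 by 2.46 (SE 0.28, adjusted p = 4.86e-05). SLAH1 (-2.75, SE 0.35, adjusted p = 0.000143) and GAT1_2.1 (-2.70, adjusted p = 0.000176) had the lowest fold changes among the genes named.

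UMAMIT36 (3.33, adjusted p = 1.3e-06), UMAMIT35 (2.83, adjusted p = 0.000109), the glutamate receptor-like gene GLR2.3 (1.68, adjusted p = 2.41e-05) and AT5G36150, here PEN3, a triterpene synthase (1.79, adjusted p = 0.0158), rose. NRT2.2 was at 7.40 (adjusted p = 7.12e-05). Both PEN3 and NRT2.2 were well above background on 2 of 3 control arrays. SKOR (-2.19, adjusted p = 1.86e-05), SAG13 (-2.22, adjusted p = 0.0308) and the receptor-like kinase gene CRK18 (-2.05, adjusted p = 0.01) fell. CRK18 had 3 probes at -2.05 to -0.62, and its value was -1.21 within the slide that held both groups and -1.50 within another scan day. NIR1 (0.63, SE 0.10, adjusted p = 0.0012) and RSL2 (0.42, SE 0.11, adjusted p = 0.0342) rose, and the call of RSL2 ended under 6 of 13 other settings. Values that did not pass were 0.49 for RSL4 (adjusted p = 0.108), 0.30 for TAR2 (0.0659), 0.26 for DWF1 (0.160), 0.18 for YUC8, 0.16 for BSK3 (0.107), 0.12 for TAA1, 0.05 for AUX1 and -0.23 for NRT1.1 (0.283).

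**Figure D2:**
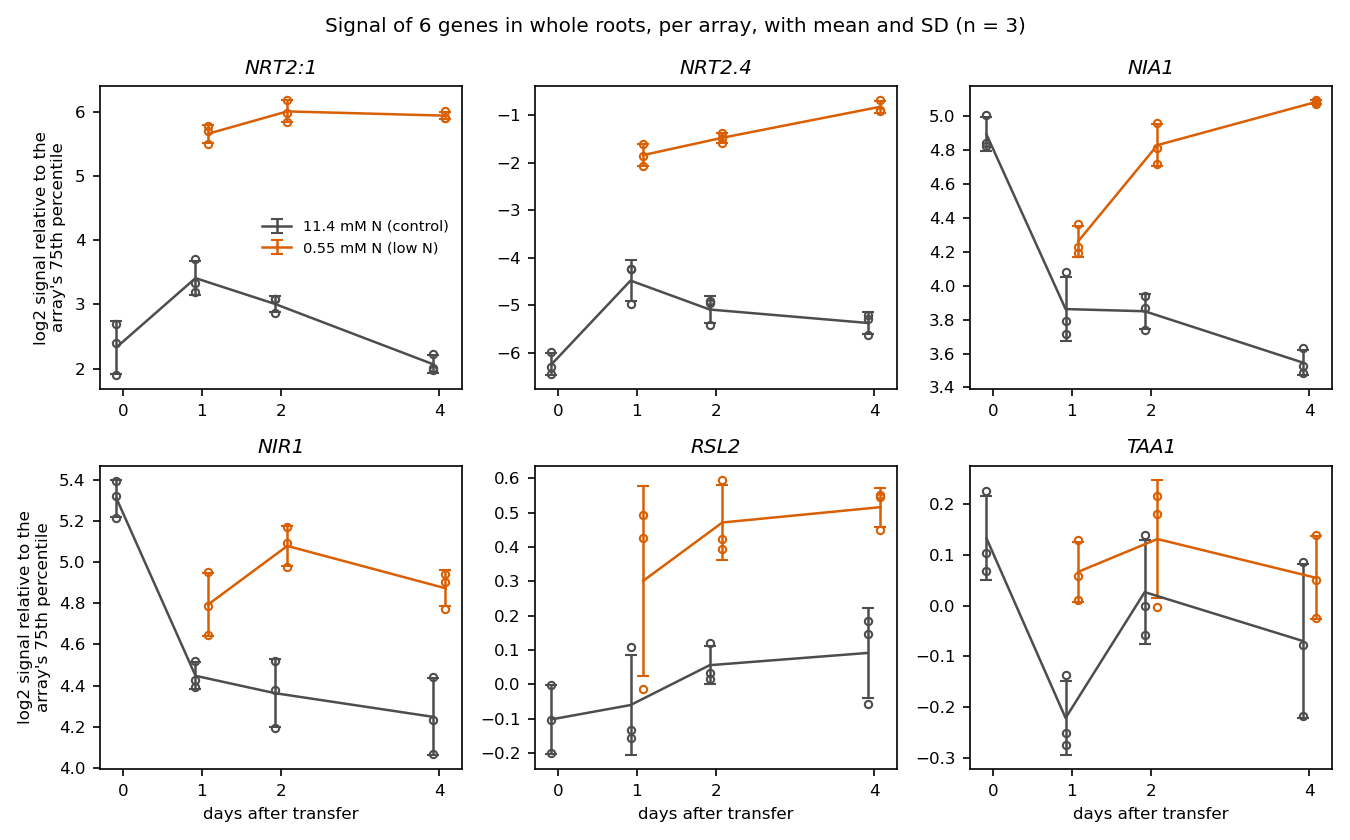
Scaled log2 signal of NRT2:1, NRT2.4, NIA1, NIR1, RSL2 and TAA1 by day, with 1 circle per array, the line and bar giving mean and SD (n = 3), control in grey and low N in orange. NRT2:1 lies at 5.66, 6.01 and 5.94 on low N and at 3.41, 3.01 and 2.07 on control medium at days 1, 2 and 4.

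Camera called 9 of the 27 lists at day 4, 5 up and 4 down. With an estimated correlation none passed (4 at an unadjusted p under 0.05), and fry called 8. Fry's calls included nitrate transport, which camera did not call. They left out sulfate (fry adjusted p = 0.209) and xylem (0.198). Root hair growth rose (10 of 21 up, 14 adjusted over the list alone, median 0.59, adjusted p = 1.03e-10, adjusted p = 0.183 with an estimated correlation). HA7 was at 1.08 (adjusted p = 0.000232) and RHS12, a pectin methylesterase, at 0.73 (adjusted p = 0.0043). Root hair patterning and transcription factors rose (3 of 17 up, 5 adjusted over the list alone, median 0.05, adjusted p = 0.0327, adjusted p = 0.143 with an estimated correlation) through RHD6 (0.53, adjusted p = 0.0012), LRL3 (0.64, adjusted p = 0.0137) and RSL2. The call ended with quantile or normexp normalization and in the value table. Nitrate reduction and assimilation rose (10 of 25 up and 2 down, 13 and 3 adjusted over the list alone, median 0.20, adjusted p = 1.12e-05, adjusted p = 0.143 with an estimated correlation). GLN1;4 was at 1.31 (adjusted p = 4.55e-07) and GDH2 at -1.05 (adjusted p = 4.55e-07). Ammonium, urea and amino acid transport rose (4 of 10 up, 5 adjusted over the list alone, median 0.35, adjusted p = 2.45e-05, adjusted p = 0.143 with an estimated correlation). DUR3 was at 1.45 (adjusted p = 4.25e-06), LHT1 at 1.08 (adjusted p = 0.000226) and AMT1;1 at 0.69 (adjusted p = 0.0016). Endodermal barriers and suberin rose (4 of 24 up, 6 adjusted over the list alone, median 0.17, adjusted p = 0.000116, adjusted p = 0.259 with an estimated correlation). The MYB transcription factor gene MYB93 was at 0.41 (adjusted p = 0.0058) and CASP4, a protein of the Casparian strip domain, at 0.53 (adjusted p = 0.0236).

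Cytokinin genes fell at day 4 (2 of 21 up and 5 down, 2 and 8 adjusted over the list alone, median -0.08, adjusted p = 0.0189, adjusted p = 0.261 with an estimated correlation). CYP735A2, also of trans-zeatin synthesis, was at -1.0 (adjusted p = 0.000514). Iron acquisition fell (2 of 29 down by either adjustment, median -0.19, adjusted p = 0.0046, adjusted p = 0.259 with an estimated correlation). COPT2 was at -1.39 (adjusted p = 0.000267) and the reductase gene FRO3 at -0.53 (adjusted p = 0.0065). Sulfate uptake (2 of 15 down, 1 up and 4 down adjusted over the list alone, median -0.23, adjusted p = 0.0327, adjusted p = 0.636 with an estimated correlation) and xylem secondary cell wall (0 of 8, median -0.16, adjusted p = 0.0265, adjusted p = 0.636 with an estimated correlation) were called down, the sulfate call ending with quantile normalization, median centring and the value table. Nitrate transport had 5 of 16 members up and 3 down (5 and 4 adjusted over the list alone), and was not called by camera. Its median was -0.21 but its mean 0.85, with a test pointing up (adjusted p = 0.409). Nitrate signalling had 4 of 23 up and 5 down (4 and 6 adjusted over the list alone, median 0.04, mean -0.09, test down, adjusted p = 0.655). LBD38, a repressor of nitrate-responsive genes, was at -0.69 (adjusted p = 0.000284) and AT3G25790, listed as the repressor HHO1, at 0.67 (adjusted p = 0.0023). Phosphate starvation response had 5 of 24 up and 5 down (6 and 5 adjusted over the list alone, median -0.09, adjusted p = 0.673). Its members included MGD2, a galactolipid synthase (0.76, adjusted p = 0.0019), and AT5G03545, the noncoding RNA gene AT4 (-1.80, adjusted p = 2e-04). CEP and CLE signalling had 1 of 13 up, AT4G32950 (3.17, adjusted p = 1.87e-07), and 2 down (3 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.327). The defence list had 1 of 12 up, FRK1 (0.80, adjusted p = 0.000952), and 2 down, PAD3 (-0.41, adjusted p = 0.01) and JAZ1 (1 and 4 adjusted over the list alone, median -0.07, adjusted p = 0.425). Of 28 auxin signalling genes 2 fell, GH3.3 (-1.27, adjusted p = 0.0015) and LBD16 (-0.59, adjusted p = 0.0065), with a list median of -0.03 (adjusted p = 0.308). Shoot markers had none of 22 past the test, 17 negative values and a median of -0.12 (adjusted p = 0.577). None of the remaining lists was called on this day. No member passed in auxin biosynthesis and transport (16 tested), meristem (6), cell cycle (20), ribosomal proteins (18), phenylpropanoids (17), autophagy (16), handling (10), low oxygen (6) or abscisic acid (5). DET2 alone fell among 18 brassinosteroid genes (-0.37, adjusted p = 0.000885) and DIN10 alone among 10 genes of sugar status (-1.07, adjusted p = 0.0273). The brassinosteroid list had a median of 0.05 and a mean just under 0.

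**Figure D3:**
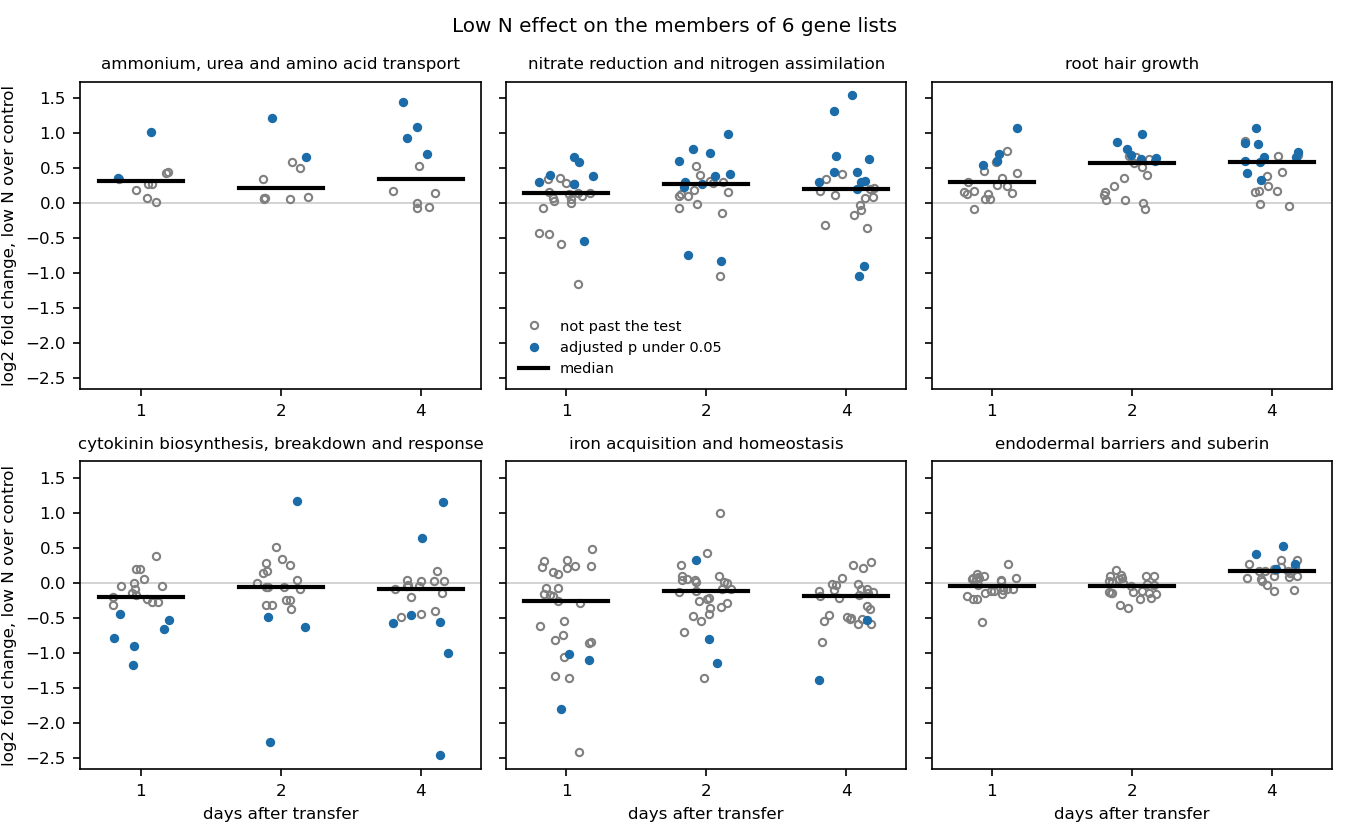
Each point is the log2 fold change of 1 member of 6 gene lists under low N at days 1, 2 and 4, filled where the adjusted p was under 0.05, with a line at the list's median. The medians of root hair growth are 0.30, 0.58 and 0.59, and those of iron acquisition -0.26, -0.12 and -0.19.

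At day 4 there were 1347 called genes, 789 up and 558 down, and 194 changed at least 2-fold. The share of calls that were up was 58.6%, and 45.6% with median centring. Leaving out control replicates 2 or 3 gave 872 and 828 calls, and leaving out low N replicates 1 or 2 gave 882 and 825. Without the 3 arrays that stand apart there were 902 calls, 810 of them among the 1347. One slide held 1 array of each group, the only arrays of their scan day. Of 593 genes called without these 2 arrays, 98.3% had the same sign there, in a test chosen after the results were seen. Values there were 4.52 for NRT2.4, 3.91 for NRT2:1, 1.45 for NIA1, -2.21 for ALMT1 and -2.54 for CKX2, while those of DIN10, FRO3 and DET2 came to -0.68, -0.33 and -0.25. On another scan day, with 2 low N arrays and 1 control array, the values were 3.99 for NRT2:1 and -2.02 for ALMT1, and 0.41 for RHS12. Probes of 1 gene ranged from -1.70 to -0.84 for GDH2, -1.07 to -0.49 for DIN10 and -0.37 to -0.12 for DET2. List medians within the slide were 0.64 for root hair growth, 0.08 for root hair regulators, 0.21 for assimilation, 0.41 for ammonium transport and 0.20 for suberin. They were -0.28 for cytokinin, -0.08 for iron, -0.25 for sulfate and 0.01 for xylem. With slide as a random block 1387 genes were called and with scan day 1424. As fixed blocks, scan day gave 858 calls and slide 164 (149 of them among the 1347). With slide 23 of the 54 named calls held, among them NRT2.4, NRT2:1, NIA1, ALMT1, CKX2, SKOR and SLAH1. The slide block ended the calls of root hair regulators (median 0.04), xylem (-0.03), iron (-0.13) and sulfate (-0.21). Medians of the others were 0.46 for root hair growth, 0.21 for assimilation, 0.41 for ammonium transport, 0.20 for suberin and -0.35 for cytokinin.

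Across the 3 days, 1792 genes were called at least once, 143 were up on each day and 144 down on each day. Down at day 1 and up at day 4 were 3 genes, named after their values were seen, GH9B17, AT1G70860 and AT4G33610. The overlap of calls in the same direction was 165 up and 167 down for days 1 and 2 (7.26 and 4.61 for independent lists), 165 and 177 for days 1 and 4 (13.6 and 7.78) and 319 and 249 for days 2 and 4 (15.9 and 8.85). Each day had its own control arrays, but slides and scan days were shared between days. A single scan day held low N arrays of days 1, 2 and 4 and control arrays of days 2 and 4 only. Among the slides, 1 held low N arrays of days 1 and 2 and another those of days 2 and 4. The days are therefore not independent of slide and scan day, which were not removed from these overlaps. Over the 20882 genes, which are not independent replicates, the fold changes correlated at r = 0.220 (rho 0.325) for days 1 and 2, 0.433 (rho 0.281) for days 1 and 4 and 0.545 (rho 0.466) for days 2 and 4. For days 1 and 2, r was -0.0021 without control day 1 replicate 2, 0.549 without control day 1 replicate 3, 0.0166 without low N day 2 replicate 2 and 0.524 without low N day 2 replicate 3. It was 0.288 for days 1 and 4 without control day 4 replicate 2, and 0.30 for days 2 and 4 without low N day 4 replicate 1. Averaged over days, 3213 genes were called, 1831 up and 1382 down, with the majority turned to 1137 up and 1262 down by median centring and to 77 and 82 among those changed at least 2-fold. The highest of the called genes with a symbol were NRT2.2 (7.14), NRT2.4 (3.6, adjusted p = 7.93e-12), UMAMIT36 (3.25), NRT2:1 (3.04) and UMAMIT35 (2.47). Among the lowest with a symbol were SKOR (-2.31, adjusted p = 6.19e-09), SAG13 (-2.27), SLAH1 (-2.16), GAT1_2.1 (-2.07) and SEN1, a dark-inducible gene (-2.05, well above background on 6 of 9 low N arrays). The lipid transfer gene LTP4, called up (adjusted p = 0.0324), was not well above background in control roots of day 2, and the defensin gene PDF1.4, called down (adjusted p = 0.0013), was not in low N roots of day 4, so no fold is given for either. Slide as a fixed block gave 60 calls (59 shared with the 3213), scan day 639, and the fit without the 3 arrays 2656. An F test of whether the low N effect differed between the days called 12 genes. Among them was NRT2.4, whose effect was 1.91 higher at day 4 than at day 1 (SE 0.28, adjusted p = 0.0297). So were NIA1 (1.14 higher, SE 0.13, adjusted p = 0.0041) and ALMT1 (-1.25, SE 0.15, adjusted p = 0.0044). With slide or scan day as a fixed block, limma called 0 genes in this test. At an unadjusted p under 0.05 there were 1332 and 1216 with these blocks and 1301 without a block, each little above the 1044 expected by chance. Without the 3 arrays it called 6.

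In control roots the days differed widely. From day 0 to day 4, CWINV5, a cell wall invertase gene, rose by 7.63 (SE 0.48, n = 3 per group, adjusted p = 2.09e-08), and the asparagine synthetase gene ASN1 by 5.91 (SE 0.68, adjusted p = 1.27e-05). Others that rose were DIR1 by 5.77, the expansin gene EXPB2 by 5.56 and the cytochrome P450 gene CYP712A1 by 4.97. CYP93D1 was not well above background at day 0 and was at least 7.71-fold higher at day 4 (adjusted p = 0.000316), and CWINV5, DIR1 and EXPB2 were well above background on 1 of 3 day 0 arrays. The cold-response regulators CBF1 (-5.51, SE 0.65, adjusted p = 1.63e-05) and CBF2 (-4.01, adjusted p = 5.86e-06), each well above background on 2 of 3 day 4 arrays, fell. So did the deadenylase gene CAF1a (-4.59, adjusted p = 1.09e-08), the heat shock factor gene HSFA6B (-4.15), JMJD5 (-4.07) and COR27 (-3.81). One slide held 2 arrays of day 0 and 1 of day 4, which was also their only shared scan day. Of 2409 genes called between these days without its arrays, 92.2% had the same sign there, in a test chosen after the results were seen. Those calls set 1 array of day 0 against 2 of day 4, with the spread taken from the other groups. Values there were 7.46 for CWINV5, 5.11 for ASN1 and -6.60 for CBF1, and with slide as a fixed block 7.91, 6.41 and -6.26. The F test over the 4 control days called 6035 genes, 1051 of them with a 2-fold change, and against day 0 there were 4779 calls at day 1, 3526 at day 2 and 4597 at day 4. Slide as a fixed block gave 1710 (1591 shared), scan day 2876 and the fit without the 3 arrays 5289. Among the lists at day 4 against day 0, camera called 9, and none with an estimated correlation (3 at an unadjusted p under 0.05). Nitrate reduction and assimilation fell (2 of 25 up and 13 down, 2 and 16 adjusted over the list alone, median -0.26, adjusted p = 2.15e-06, adjusted p = 0.0863 with an estimated correlation). NIA1 was at -1.35. Suberin (2 of 24 up and 9 down, 2 and 11 adjusted over the list alone, adjusted p = 0.0069, adjusted p = 0.526 with an estimated correlation), cell cycle (1 of 20 up and 6 down, 1 and 7 over the list alone, adjusted p = 0.0153, adjusted p = 0.526 with an estimated correlation) and nitrate signalling (1 of 23 up and 7 down, 2 and 9 over the list alone, adjusted p = 0.018, adjusted p = 0.365 with an estimated correlation) fell, and ribosomal proteins rose (3 of 18 by either adjustment, adjusted p = 0.0243, adjusted p = 0.552 with an estimated correlation). Auxin biosynthesis (adjusted p = 0.0374), auxin signalling (0.0307), meristem (0.0374) and defence (0.0489) were also called down, the defence list with a median of -0.28 but a mean of 0.13 (adjusted p = 0.526, 0.526, 0.281 and 0.526 with an estimated correlation). List medians within the slide and with slide as a fixed block were -0.25 and -0.27 for assimilation, -0.08 and -0.05 for suberin, -0.09 and -0.15 for cell cycle, -0.10 and -0.12 for nitrate signalling and 0.13 and 0.14 for ribosomal proteins. Those of auxin biosynthesis were -0.15 and -0.14, of auxin signalling -0.16 and -0.17, of meristem -0.17 and -0.25 and of defence -0.42 and -0.28. Shoot markers had a median of -0.12, 1 of 22 down, and -0.92 within the slide. The direction of lists over time in control roots was computed under a single scaling.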

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

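The tests for handling, for slide at day 4, for the errors of the blocked fits and for the suberin list were chosen after the results were seen.

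The low N effect differed between days for 12 genes by limma's F test. Between day 4 and day 1 it differed by -1.30 for UMAMIT33 (adjusted p = 0.013), -1.25 for ALMT1 (0.0044), 1.01 for MLO14 (0.0042), 1.14 for NIA1 (0.0041), 1.42 for GH9B17 (0.0017), 1.62 for NRT2:1 (0.0346) and 1.91 for NRT2.4 (0.0297). For NRT2:1 the low N means of days 1 and 4 were 5.66 and 5.94 and the control means 3.41 and 2.07. Most of its difference thus lay in control roots. For NRT2.4 the low N means were -1.84 and -0.82 and the control means -4.48 and -5.37, so both media moved. The calls of NRT2:1, NRT2.4 and NIA1 ended under 7 of 13, 8 of 12 and 3 of 13 other settings. The other 5, AT2G28270, AT2G41810, AT4G38340, AT5G26200 and AT5G54700, carry no symbol and are named after their values were seen. In 3 of 100 exchanges of days among arrays as many genes were called, the real one included. This share lay under the 0.05 set beforehand. With 100 exchanges it is imprecise, so it does not exclude a random exchange of days. The exchanges took no account of slide or scan day, and with either as a fixed block limma called 0 genes. At an unadjusted p under 0.05 there were 1332 and 1216 with these blocks and 1301 without a block, against 1044 expected by chance. The day 4 minus day 1 differences of the 12 genes then came to 0.95 and 0.96 times in the median (0.76 to 1.17 and 0.74 to 1.18), and their standard errors to 1.385 and 1.33 times. With 6 and 9 residual degrees of freedom in place of 14, each of the 12 had an unadjusted p under 0.05. For these 12, errors grew more than differences shrank. They were chosen from the same arrays, so a slide or scan share in their calls is not excluded. Other exchanges called 1902 and 333 genes, and what set them apart was not identified.

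List medians also differed between days by camera, and none of these passed with an estimated correlation. From day 1 to day 2 the shift was -0.091 for ribosomal proteins, 0.14 for cytokinin and -0.12 for defence, and from day 1 to day 4 it was -0.16 for ribosomal proteins and 0.23 for suberin. From day 2 to day 4 it was 0.25 for suberin, 0.10 for autophagy and 0.15 for defence. At an unadjusted p under 0.05, the estimated correlation gave 0, 1 and 3 lists in these 3 comparisons and fry 3, 3 and 2, with 0 after adjustment. Among probes with no matched locus, outside the comparisons above, 59, 54 and 103 differed at days 1, 2 and 4.

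By camera, the endodermal barrier and suberin list lay lower at day 2 and higher at day 4 under low N. Its day 2 median was only -0.04, with 0 of 24 members past the test (fry adjusted p = 0.414). That day 2 call ended with quantile, normexp and the value table. In control roots the list median was -0.14 from day 0 to day 4. The shift was not split into control and low N parts. Of 24 members, 22 had a positive difference between these days (median 0.25, adjusted p = 9.69e-13, adjusted p = 0.07 with an estimated correlation). None of the 24 passed the test over all genes, and 3 did when adjusted over the list alone. The shift was 0.206 without the 3 arrays that stand apart, at least 0.208 under 4 other scalings and 0.25 with slide as a fixed block, so none of these accounts for it alone. A change of barrier gene expression between days is a hypothesis that may hold, but the call rests on the preset correlation, which leaves it open.

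Slide as a fixed block ended most low N calls. Of 593 genes called at day 4 without the 2 arrays of the slide that held both groups, 98.3% had the same sign within that slide, as had 96.7% of the 752 genes of day 2 and 89.4% of the 651 of day 1 in the same day 4 difference, which argues against slide differences as the whole cause. The standard errors of the day 1 calls grew to 1.79 times while the fold changes stayed at 0.96 times in the median, with 6 residual degrees of freedom in place of 14. These 651 genes were called from the same arrays, so the ratios do not exclude a slide share in their fold changes. At an unadjusted p under 0.05, the day 1 test held 3582 genes without the block and 1514 with it. Loss of precision may account for many lost calls, but its share is not settled. A slide share in single genes and lists of day 1, such as iron acquisition, stays open, since no slide held both groups of that day.

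With the 6 arrays of a day there are 10 splits, so the share of splits as large cannot go under 0.1, and the real split alone (1 of 10) gave the highest count each time. For genes the real count and the highest other were 651 and 0 at day 1, 752 and 1 at day 2, and 1347 and 0 at day 4. For lists they were 9 and 8, 11 and 9, and 9 and 8, so other splits called nearly as many lists. For the average over days 1 of 100 exchanges, the real one, gave 3213 and the highest other 4. The real count thus lay far above every other exchange drawn, though a share from 100 exchanges is imprecise. These exchanges took no account of slide or scan day, which were not balanced between the media. They therefore do not exclude a slide or scan day share. With slide and scan day as fixed blocks the average gave 60 and 639 calls.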

How the results depend on the processing

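Leaving out the 3 arrays that stand apart, the share of spots well above background as a covariate, scan day as a fixed block and the test of unmatched probes were chosen after the data were seen. Of 204 calls and values of named genes, 61 kept direction and side of the threshold with slide as a fixed block, 119 with scan day, 156 without the 3 arrays, 179 with median centring, 181 with quantile, 181 with normexp and 175 in the value table. The cause was not tested for the changes below except where fewer arrays, genes or degrees of freedom make it plain. Dim probes limit the fold changes that signal over background allows.

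Genes called at days 1, 2 and 4 were 2, 1 and 164 with slide as a fixed block (60 for the average, 0 for the day test, 1710 for control days), and 10, 249 and 858 with scan day (639, 0 and 2876). Limma's day test then held 1332 and 1216 genes at an unadjusted p under 0.05, against 1301 without a block and 1044 expected by chance. As random blocks, slide gave 432 at day 1 and scan day 318. Array weights gave 1925, 1435 and 3357 (5701 for the average, 35 for the day test). Without the 3 arrays there were 312 at day 1, 382 at day 2 and 6 in the day test. The covariate gave 295 at day 1 and median centring 374. With the 2-fold threshold there were 78, 128 and 194 (159 for the average, 1051 for control days), and with only the groups compared 55, 318 and 733 (3967 for control days). Leaving out 1 array gave 269 to 414 at day 1, 395 to 699 at day 2 and 825 to 1165 at day 4.

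With an estimated correlation 0, 0 and 0 lists were called at days 1, 2 and 4 (6, 5 and 4 at an unadjusted p under 0.05; fry called 8 each day). At day 2 the value table called 7 lists, and leaving out 1 array gave 7 to 12. Of the 29 camera calls over these days, 25 held without the 3 arrays that stand apart. With scan day as a fixed block 23 held, and with slide 17. The iron list at day 2 turned to 0.0146 with slide as a fixed block. The mean correlation of low N effects between days, 0.3992, was 0.6095 with normexp, 0.5032 in the value table, 0.0883 with no filter, 0.6015 with the filter on all arrays, 0.5052 without the 3 arrays, 0.5694 with the covariate and 0.2909 to 0.5495 leaving out 1 array. For days 1 and 2 it turned to -0.1211 with no filter and ranged from -0.0021 to 0.5489 leaving out 1 array.

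Signs turned for these genes, most of which had passed no test. RSL4 at day 1 was 0.0124 with normexp, 0.0267 with quantile, 0.0169 with median centring, 0.0147 in the value table and -0.1986 to 0.1585 leaving out 1 array, and at day 2 it was -0.158 with slide as a fixed block. AUX1 at day 1 was -0.0227 with normexp, -0.0266 in the value table, -0.0586 with slide, -0.0889 with scan day and -0.018 with the covariate, and at day 4 it was -0.0206 to 0.0959 leaving out 1 array. DWF1 was -0.0138 and -0.0619 at days 1 and 2 in the value table, -0.0083 and -0.0579 with the mean of its probes, and at day 1 -0.011 with slide and -0.0466 with scan day. BSK3 at day 2 was -0.0036 with median centring, YUC8 at day 4 -0.1046 with slide, and RPS6 at day 1, which had been called, -0.086 in the value table.

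Same-numbered arrays showed no clear pairing in their deviations from group means. They correlated at -0.38 to 0.30, -0.33 to -0.02 and -0.48 to 0.15 at days 1, 2 and 4. Of the low N samples, 0, 0 and 1 correlated best with their own number. The replicate block gave 19 genes in the day test, against 12 without it. It gave 720, 833 and 1429 at days 1, 2 and 4, against 651, 752 and 1347. Since the block raised these counts, pairing by replicate number is not settled.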

Other observations

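The handling test and the test on the slide holding days 0 and 4 were chosen after the results were seen, as were the gene families described here.

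Families grouped by symbol prefix were tested like the lists under a single scaling, and none of 211 passed with an estimated correlation (10, 11 and 16 at an unadjusted p under 0.05 at days 1, 2 and 4). By chance, a share of 0.05 of the 211 families is expected under that threshold. With the preset correlation 16, 7 and 2 were called, of which some are described here. Root hair specific (RHS) genes had 2, 5 and 8 of 9 members up at days 1, 2 and 4 (medians 0.39, 0.60 and 0.58; adjusted p = 0.000593, 3.81e-07 and 9.12e-10; adjusted p = 0.775, 0.527 and 0.567 with an estimated correlation), of which the root hair list also holds RHS12 and RHS19. Amino acid permeases (AAP) had 1 of 8 up at day 1 and 4 of 8 at day 2 (medians 0.36 and 0.44, adjusted p = 0.0185 and 0.000871, adjusted p = 0.579 and 0.254 with an estimated correlation), with AAP7 at 0.92 on day 2. At day 4, 3 of 8 were up and the family was not called (adjusted p = 0.0753). Transporters with an NRT symbol had 3, 3 and 4 of 12 up (medians 0.29, 0.55 and 0.068; adjusted p = 0.0026, 0.001 and 0.0358; adjusted p = 0.507, 0.254 and 0.567 with an estimated correlation). These were NRT2:1, NRT2.2, NRT2.4 and, at day 4, NRT1.8 (1.27, adjusted p = 0.0162). The wider nitrate transport list, which holds this family except NRT1.7 and NRT1.9, was not called by camera. Fry called it up on each day (adjusted p = 0.002, 4.25e-05 and 2.58e-05). Beta-glucosidases (BGLU) had 2 of 29 down at day 1 and 1 of 29 at day 2 (medians -0.21 and -0.12, adjusted p = 0.000593 and 0.000871, adjusted p = 0.618 and 0.610 with an estimated correlation). At day 4, 4 of 29 were down and the family was not called (adjusted p = 0.243). In control roots from day 0 to day 4, 13 of 25 GSTU glutathione transferases were up (median 0.31, adjusted p = 0.0069, adjusted p = 0.839 with an estimated correlation) and 5 of 9 CYCB cyclins down (median -0.28, adjusted p = 0.0092, adjusted p = 0.839 with an estimated correlation).

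Control roots of day 4 differed from those of day 0 in 11 of 14 listed clock genes, 4 up and 7 down, and the 14 had a median absolute log2 difference of 1.13 against 0.162 for all genes. The dawn gene CCA1 was higher by 2.2 and LHY by 2.22, while the afternoon gene PRR3 was at -2.33 and the evening gene TOC1 at -1.26. This is consistent with harvest at another time of day. Against slide and scan batch as the whole cause, 92.2% of 2409 genes called off the slide that holds days 0 and 4 had the same sign within it. The off-slide calls rest on 1 day 0 array, assumed to vary like the other groups. The planned test compared no day 4 array. It took 4125 genes called between days 2 and 0 and their sign between days 1 and 0 on another slide. With 74.3% of the same sign, it left a batch cause undecided. Heat, touch or cold during handling cannot be told apart from the day by the handling list. Called lower at day 4 were TCH3 (-0.58), TCH4 (-0.84), DREB2A (-1.03), LTI78 (-0.68) and RHL41 (-0.72), while HSP17.4 (1.94) was called higher. The other members did not pass, and camera did not call the list of 10 (median -0.16, SD 1.16, adjusted p = 0.197). Transfer and age, which the design also changes between these days, stay open and untested. The control F test gave 6035 genes in the real order, the highest count of 100 exchanges. The exchanges ignored slide and scan day, so they do not exclude a share of either. With these as fixed blocks there were 1710 and 2876 genes. The highest other exchange gave 5105 and kept the 3 day 0 arrays together. This points to the distance of day 0 as a structure of the samples.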
